A study of Mus musculus with 19 samples.

How the data were processed

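RNA from the livers of 19 male C57BL/6 mice was measured on Affymetrix expression arrays, 1 array per sample. The mice were 10 to 12 weeks old and were killed 2 h after removal of 85% of the liver. They fall into 4 groups by genotype: 5 wild-type samples (WT), 6 without Ager (Ager_null), 4 without Myd88 (Myd88_null) and 4 without both genes (Ager_Myd88_null). Group and replicate number were taken from the sample titles. The labels describe RNA per mouse, so the samples were treated as separate animals. Arrays of a group differed by a root mean square of at least 0.328 (log2) over the tested genes, so none looked like a repeat of another.

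The authors deposited log2 expression values per probe set, made with GCRMA version 2.16 per the submitters' processing notes, and these values were used as given. GCRMA corrects each array for background with probe sequence, normalizes across arrays and summarizes the probes of a set. Further details of the normalization and filtering are not given in the sources used here. Per the labels' protocols, RNA was amplified and biotin-labelled with a 3' IVT kit. The deposited log2 values ran from 0.744 to 15.6, with array medians between 2.75 and 2.83. The extraction text in the labels speaks of glomeruli, while the source and tissue labels give liver, and the levels of liver and kidney markers are reported with the results.

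Of 45101 probe sets, 64 were array controls and were left out. In the platform annotation, 34945 of the others carried 1 gene symbol, 932 several and 9160 none. Probe sets with several symbols or none were not used for genes, and those with none were tested separately. Each of 18193 genes was represented by the probe set with the highest mean over all arrays. A gene entered the tests if its value was over log2 4 on at least 4 arrays, which left 8515 genes and removed 9678. Of the tested genes, 5419 have several single-gene probe sets.

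Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the 4 groups in 1 fit so that they shared an estimate of the spread. There were 7 comparisons, the last being the interaction, (Ager_Myd88_null minus Ager_null) minus (Myd88_null minus WT). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors of the fit, and errors of group means are SDs. On simulated arrays with 200 changed genes among 8515 for Ager_null against WT, 81.4% of changes of 1 and 98.8% of changes of 2 (log2) were recovered. For the interaction these shares were 51.5% and 92.8%. The simulated genes were drawn independently, with the SD of a gene the same on all arrays. The shares therefore leave out effects shared by the genes of an array and arrays of unequal spread. The number of arrays limits the precision, and no depth per sample applies to arrays.

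The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. There were 21 pathway lists and 12 lists of cell type or tissue markers, of which 28 had at least 3 tested members and so a set test. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They were also tested with fry, which asks whether the members of a list move one way and does not compare them with other genes. Genes are named by this rule: Ager and Myd88, the 10 largest rises and 10 largest falls of a comparison among called genes whose groups did not overlap (for the interaction, the 10 largest estimates), and up to 4 members of a list with the smallest p. Lists are named in a comparison where camera passed or at least 3 members were called. A list called shifted passed camera at the preset correlation. In Ager_null against WT the estimated correlation was 0.602 for cholesterol synthesis, 0.765 for Kupffer cell markers and 0.021 for the Toll-like receptor pathway. Where it lies far over 0.01, the camera p at the preset is too small. Gene models with only a Riken or Gm number count but are named only where fewer than 5 others are left. Values of genes that did not pass are given without a direction verb.

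Genes near the deleted loci were found from the order of genes in a RefSeq gene table of the mouse assembly GRCm38.p6, as the 150 annotated genes on each side of Ager (chromosome 17) or Myd88 (chromosome 9), and compared with all other tested genes by Fisher's exact test, two-sided. No coordinates are printed, since the build behind the array annotation is not given in the sources used here. The sample descriptions also carry an S number per array, whose meaning is not stated. Arrays were grouped into S 1 to 6, S 7 to 12 and S 13 to 20 and this range was tried as a block. List tests under the blocks and other scalings, and the whole-chromosome counts, were added after the data were seen. All 6 Ager_null arrays lie in S 13 to 20, together with WT 5 and Myd88_null 4. Other alternatives were no filter or a filter at log2 6, a floor at log2 4, the mean of a gene's probe sets or every probe set, quantile normalization or median centring of the deposited values, a trended robust fit, array weights, a fit of only the groups compared, a replicate block, a minimum change of 1 (log2), and leaving out each array. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.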

Results

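Gene expression was measured in 19 mouse livers taken 2 h after 85% liver resection, when the remnant enters the priming phase of regeneration. Ager encodes RAGE, a cell-surface receptor for ligands such as HMGB1 and S100 proteins, and Myd88 encodes the adaptor through which most Toll-like receptors and the IL-1 receptor signal. The design asks what the loss of each gene, or of both, does to the early response. There were 5 WT, 6 Ager_null, 4 Myd88_null and 4 Ager_Myd88_null livers. No liver without resection was analysed here, so all differences are between genotypes after resection. Correlations between arrays lay between 0.948 and 0.993 over the 8515 tested genes. Myd88_null 4 stood apart, with a median correlation of 0.965 against at least 0.979 for every other array. Hepatocyte markers had a median level of 14.2 (log2) over all arrays. Of 13 kidney and glomerulus markers on the array, 0 were over log2 4 on all arrays, and the highest mean among them was 4.11 for Podxl.

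Myd88 was lower in both groups that lack it. Its level was 5.55 ± 0.29 (log2, SD, n = 5) in WT, 5.91 ± 0.38 (n = 6) in Ager_null, 3.49 ± 0.34 (n = 4) in Myd88_null and 3.45 ± 0.58 (n = 4) in Ager_Myd88_null. The lowest array of the groups with Myd88 read 5.24 and the highest of the groups without it 3.86, so each array matched its Myd88 label. The brighter of the pair of Ager probe sets read about the same in all groups, at 3.26 ± 0.23 in WT (n = 5), 3.10 ± 0.22 in Ager_null (n = 6), 3.28 ± 0.11 in Myd88_null (n = 4) and 3.37 ± 0.20 in Ager_Myd88_null (n = 4). The other read 2.24 ± 0.10, 2.40 ± 0.03, 2.195 ± 0.12 and 2.52 ± 0.08 in the same order, slightly higher in the groups without Ager. These values are under the filter, so they check nothing about the Ager labels.

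**Figure D1:**
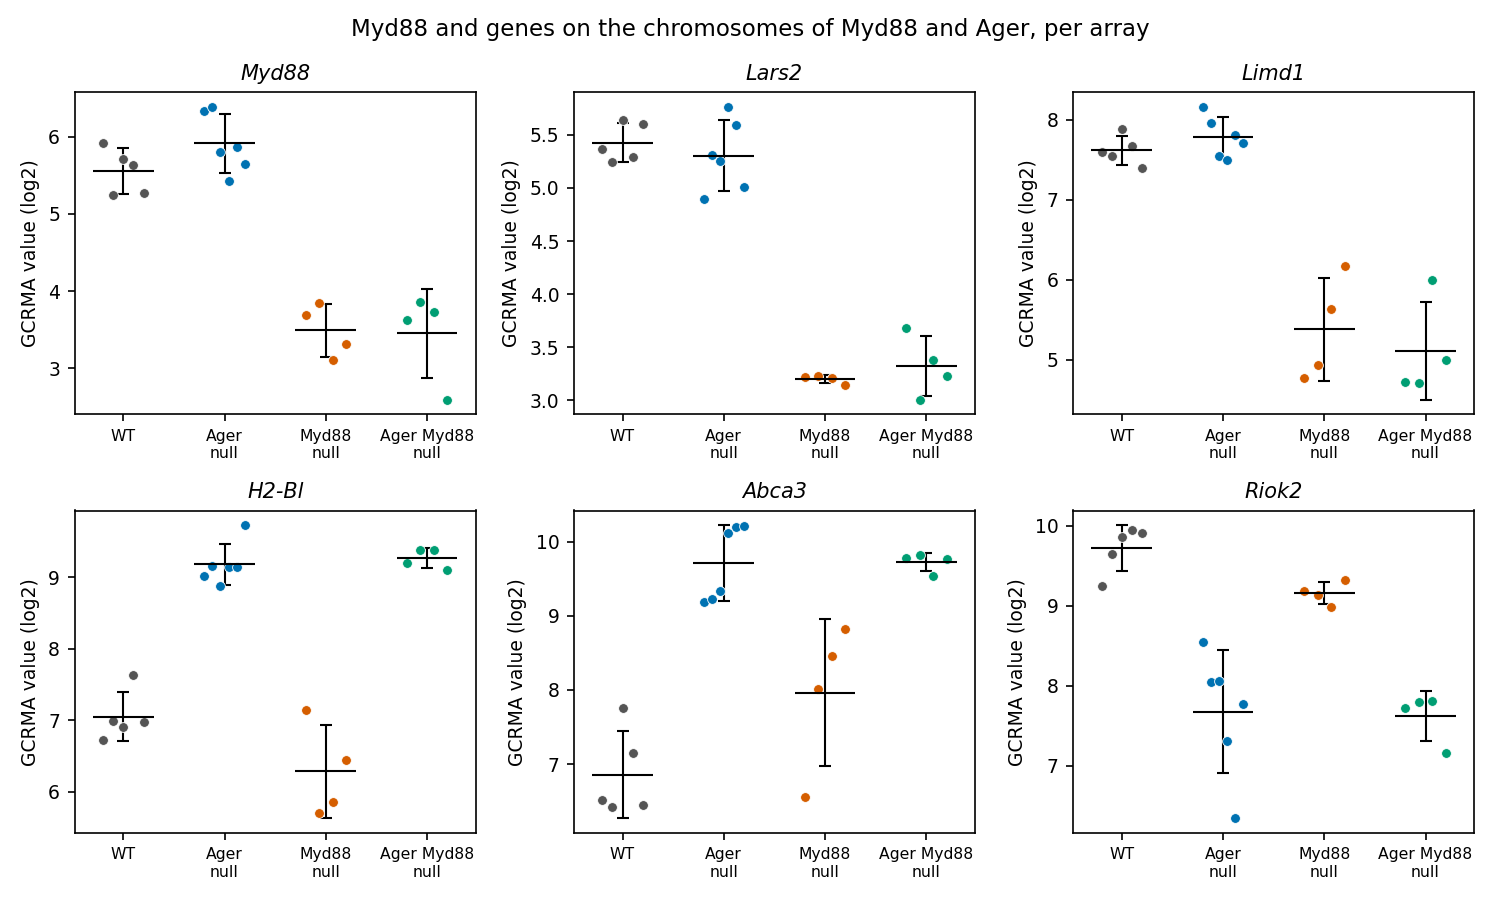
GCRMA values (log2) of Myd88 and of 5 of the named genes on the chromosomes of Myd88 (Lars2, Limd1) and Ager (H2-Bl, Abca3, Riok2), picked for display after their values were seen; each point is an array, lines are group means and bars SDs. Myd88 averaged 5.55 in WT and 3.49 in Myd88_null, and H2-Bl 7.05 in WT and 9.18 in Ager_null.

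Loss of Ager alone was compared with WT first. H2-Bl, a nonclassical class I histocompatibility gene, was higher in Ager_null (2.13 ± 0.22, log2, SE), as was the lipid transporter gene Abca3 (2.85 ± 0.34). Among the other large rises were the cadherin gene Fat1 (1.94 ± 0.41), Zmynd8 (1.42 ± 0.31), the immunoglobulin A heavy chain gene Igha (1.35 ± 0.28), Sowahb (1.29 ± 0.29), Atxn2 (1.15 ± 0.21), Tspyl4 (1.14 ± 0.24), Eps8l2 (1.14 ± 0.21) and Prdm2 (1.14 ± 0.25). Riok2, a kinase of ribosome maturation, fell by 2.05 ± 0.28, and Lgals1, which encodes galectin-1, fell by 1.40 ± 0.22. The zinc finger genes Zfp945, Zfp944, Zfp943 and Zfp58 fell by 1.59, 1.25, 0.98 and 0.86, Acyp2 by 1.15, Ccdc122 by 0.96 and the transcription factor gene Klf6 by 0.82. Adjusted p-values of these genes in limma were between 0.00011 and 0.048. With values under log2 4 set to 4, Zmynd8 (0.85), Tspyl4 (0.43) and Zfp58 (-0.32) lost the call and Zfp945 was at -0.75. Of the named genes, H2-Bl, Abca3, Riok2, Zfp945, Zfp944 and Zfp943 lie on chromosome 17 with Ager.

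In all, 107 genes differed between Ager_null and WT, 71 higher and 36 lower. The groups did not overlap for 73 of them and for 315 of all 8515 tested genes, where chance gives 0.433%, and 1839 genes had an unadjusted p under 0.05 against 425.8 by chance. Gluconeogenesis and glycogen genes were shifted up (camera adjusted p = 0.010, median 0.18), with 0 of 20 members called and 0 when adjusted over the list alone. Its members with the smallest p were Irs1 (1.36 ± 0.42), Slc37a4 (0.35 ± 0.14), Irs2 (0.91 ± 0.39) and Foxo1 (0.50 ± 0.22). Heat shock genes were shifted up (adjusted p = 0.037, median 0.23), with 1 of 15 called, the co-chaperone Stip1 (0.59 ± 0.14), and 6 when adjusted over the list alone, among them Hspa4l (1.11 ± 0.28) and Hsph1 (1.39 ± 0.42). Stellate cell and fibroblast markers were shifted up (adjusted p = 0.010, median 0.55). Of 13, the collagen gene Col1a2 was called (0.72 ± 0.15, but not with values under log2 4 set to 4, at 0.34), and 4 passed when adjusted over the list alone, among them Reln (0.99 ± 0.27) and Pdgfrb (0.65 ± 0.18). The adjusted p of these lists with an estimated correlation was 0.91, 0.91 and 0.84. In the other 30 lists, 8 members were called. With the deposited values quantile-normalized again the split was 51 higher and 43 lower, and with median centring 50 and 41. With the S range as a block 59 genes were called, 20 higher and 39 lower and 11 of them among the 107, gluconeogenesis had a camera adjusted p of 0.266, heat shock genes had 0.549, and the median size of the 107 against WT 5, the WT array in the S range of all Ager_null arrays, was 0.938 (0.80 against all WT arrays), for genes that were called with that array among them.

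Loss of Myd88 alone was likewise compared with WT. Lars2, the mitochondrial leucyl-tRNA synthetase gene (-2.23 ± 0.17), and Limd1, which encodes a LIM domain protein (-2.24 ± 0.27), were lower, both on chromosome 9 with Myd88 itself (-2.06 ± 0.25). Cd207, which encodes the lectin langerin, fell by 1.59 ± 0.24, the histone methyltransferase gene Setdb2 by 1.22 ± 0.23 and Nip7 by 0.79 ± 0.16. Zfp979 (2.05 ± 0.29), Igha (2.04 ± 0.31), the interleukin-6 receptor gene Il6ra (1.55 ± 0.32) and the integrin gene Itga9 (1.55 ± 0.16) rose. So did Postn, which encodes the matrix protein periostin (1.34 ± 0.21), Crim1 (1.26 ± 0.22), Zcchc14 (1.21 ± 0.22), Myrf (1.14 ± 0.23), Myo5b (1.07 ± 0.21) and Jup (1.06 ± 0.21). Adjusted p-values in limma were between 5.6e-07 and 0.035. Lars2, Myd88 and Cd207 averaged under log2 4, the level of the filter, in Myd88_null, and Itga9, Zfp979 and Igha in WT. When values under log2 4 were set to 4, Lars2 was at -1.43, Myd88 at -1.55, Zfp979 at 1.47 and Igha at 1.93, and Itga9 (0.57) and Cd207 (-0.41) lost the call.

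There were 34 genes that differed between Myd88_null and WT, 27 higher and 7 lower, and the groups did not overlap for 29 of them and for 385 of all tested genes (chance 1.59%). At an unadjusted p under 0.05 there were 1666 genes. NF-kB targets and cytokines were shifted down (camera adjusted p = 0.00019, median -0.38). Of 19 members 0 were called and 3 passed when adjusted over the list alone, and the smallest p belonged to Cxcl10 (-1.44 ± 0.39), Ccl2 (-1.04 ± 0.29), Irf1 (-0.43 ± 0.14) and Cxcl1 (-2.31 ± 0.87). Cholesterol synthesis genes were shifted down (adjusted p = 1.2e-06, median -0.52), with 0 of 20 called and 19 of 20 below WT, among them Pmvk (-0.76 ± 0.25), Idi1 (-0.83 ± 0.29), Cyp51 (-0.58 ± 0.21) and Mvd (-1.29 ± 0.52). Kupffer cell and macrophage markers were shifted down (adjusted p = 1.9e-06, median -0.59), with 0 of 17 called. They included Adgre1 (-1.04 ± 0.36), Lyz2 (-1.26 ± 0.53), Vsig4 (-0.89 ± 0.43) and C1qa (-0.82 ± 0.40). The adjusted p with an estimated correlation was 0.402 for NF-kB targets and 0.859 for the other pair of lists. The Kupffer cell score of Myd88_null 4 was -1.74, and without that array the list had a median of -0.20 (adjusted p = 0.0208). In the other 30 lists, 1 member was called. The split was 4 higher and 7 lower with quantile normalization and 5 and 7 with median centring. The median size of the 34 genes was 0.919, 1.06 and 1.34 within S 1 to 6, S 7 to 12 and S 13 to 20, the arrays on which they were called, and with the S range as a block 86 genes were called, all 34 among them.

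Loss of both genes went with differences from WT on the chromosomes of both. H2-Bl (2.22 ± 0.24), Abca3 (2.87 ± 0.38), Meiob (1.77 ± 0.29), Tbl3 (1.02 ± 0.19) and the tubulin gene Tubb5 (0.83 ± 0.14) on chromosome 17 and Itga9 (1.44 ± 0.16) on chromosome 9 were higher than in WT. Limd1 (-2.51 ± 0.27), Lars2 (-2.10 ± 0.17) and Myd88 (-2.10 ± 0.25) on chromosome 9 and Tedc2 (-2.20 ± 0.38), Riok2 (-2.10 ± 0.31), Zfp945 (-1.81 ± 0.37), Zfp944 (-1.44 ± 0.22) and Gfer (-0.93 ± 0.16) on chromosome 17 were lower. Elsewhere in the genome Igha (2.17 ± 0.31), Postn (1.17 ± 0.21), the potassium channel gene Kcnj8 (0.89 ± 0.16) and Gucy1a1 (0.84 ± 0.13) rose and the chemokine gene Cxcl10 fell by 1.88 ± 0.39. Adjusted p-values in limma were between 1.1e-06 and 0.044. When values under log2 4 were set to 4, Lars2 was at -1.43 and Myd88 at -1.55, and Itga9 (0.47) and Zfp945 (-0.76) lost the call. Gfer is called from its brightest probe set, and the mean of its probe sets gives 0.87.

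Ager_Myd88_null and WT differed in 27 genes, 16 higher and 11 lower, with 26 of them and 324 of all tested genes not overlapping (chance 1.59%) and 730 at an unadjusted p under 0.05. NF-kB targets and cytokines were shifted down (camera adjusted p = 2.5e-12, median -0.29), and it was the only list of all 7 comparisons to keep its call with an estimated correlation (adjusted p = 0.0059). In fry, which tests whether the members move one way and does not set them against other genes, the adjusted p was 0.018. It was the only list of this comparison to pass in fry, and in every other comparison 0 lists passed in fry. Of 19 members 1 was called, Cxcl10, and 6 passed when adjusted over the list alone. Cxcl1, a neutrophil chemokine, was at -3.70 ± 0.87, Nfkbiz at -1.17 ± 0.29 and Ccl2 at -1.15 ± 0.29.

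Another 7 lists were shifted down in camera, each with 0 members called over all genes. These were acute phase and IL-6/STAT3 genes (adjusted p = 0.00013, median -0.13), cholesterol synthesis (8.4e-07, median -0.34), immediate early genes (0.028, median -0.11), the circadian clock (0.028, median -0.28), glucocorticoid-responsive genes (0.036, median -0.03), fatty acid and triglyceride synthesis (0.036, median -0.09) and xenobiotic metabolism (0.048, median -0.03). Their adjusted p with an estimated correlation was between 0.636 and 0.706. Adjusted over the list alone, 1 acute phase gene passed, Saa3 (1.33 ± 0.35), which stood above WT while Saa2 (-1.44 ± 0.46), Saa1 (-0.99 ± 0.38) and Socs3 (-0.83 ± 0.38) stood below. In the remaining 6 of these lists 0 members passed when adjusted over the list alone. The smallest p in each belonged to Pmvk (-0.61 ± 0.25), Junb (-0.52 ± 0.19), Per2 (-0.87 ± 0.49), Fkbp5 (-0.87 ± 0.28), Thrsp (-0.39 ± 0.23) and Cyp3a13 (-0.20 ± 0.11). Immediate early genes, the clock, glucocorticoid-responsive genes, fatty acid synthesis and xenobiotic metabolism had adjusted p-values of 0.0844, 0.0844, 0.0844, 0.115 and 0.115 after quantile normalization. With the S range as a block, fatty acid synthesis, the clock and xenobiotic metabolism were at 0.132, 0.0982 and 0.109. In the other 25 lists, 2 members were called. The median size of the 27 genes was 1.58 within S 1 to 6 and 1.35 within S 7 to 12, the arrays on which they were called.

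**Figure D2:**
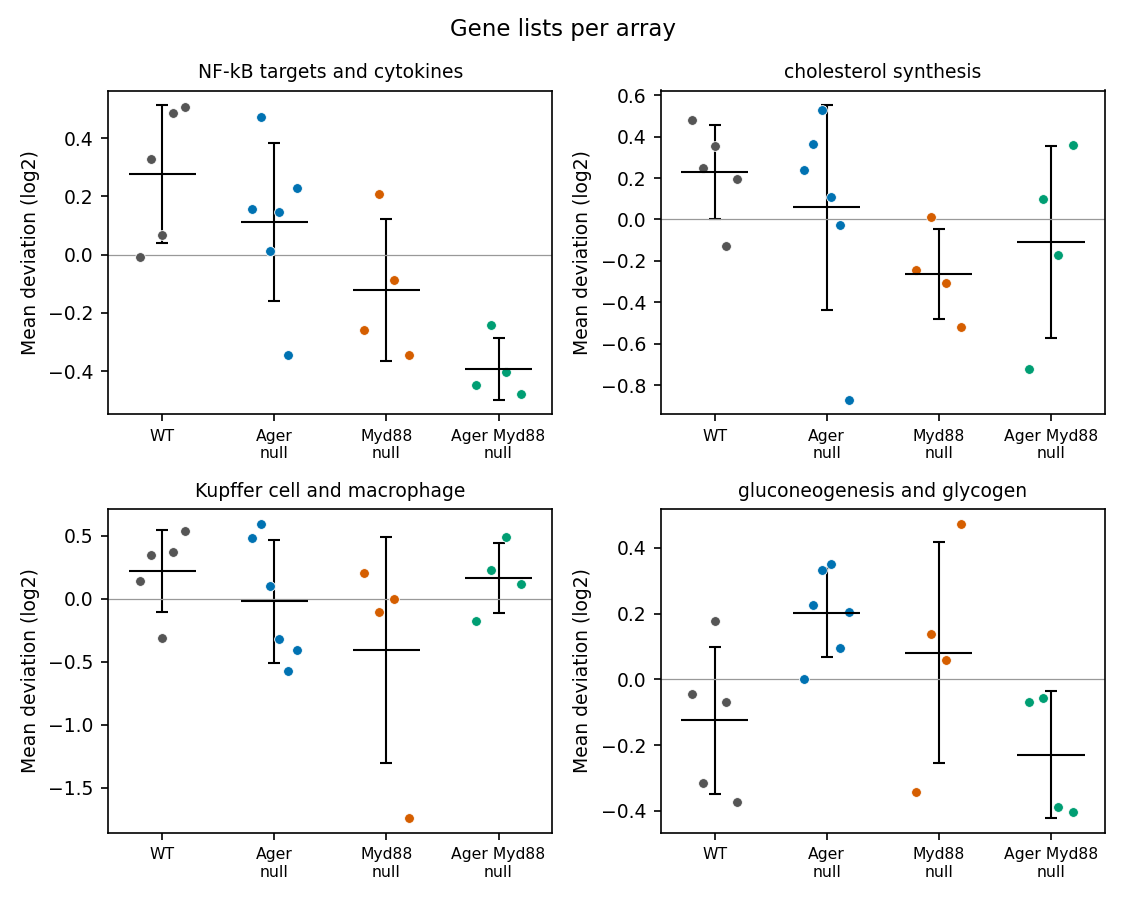
Mean deviation of the members of 4 lists (NF-kB targets and cytokines, cholesterol synthesis, Kupffer cell and macrophage markers, gluconeogenesis and glycogen) from their mean over all arrays (log2), per array, with group means and SDs as lines and bars. All 4 Ager_Myd88_null arrays lie below 0 for NF-kB targets and cytokines, and Myd88_null 4 lies at -1.74 for Kupffer cell and macrophage markers.

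Where Ager was already absent, livers that also lacked Myd88 had lower Limd1 (-2.67 ± 0.26), Myd88 (-2.46 ± 0.24) and Lars2 (-1.98 ± 0.16) and higher Itga9 (1.33 ± 0.15). They also had lower levels of the cathepsin gene Ctse (-2.65 ± 0.50), the kinase gene Pim1 (-2.08 ± 0.33), Foxq1 (-1.96 ± 0.45), Fkbp5, a co-chaperone of the glucocorticoid receptor (-1.61 ± 0.27), Trim2 (-1.49 ± 0.26) and Ceacam1 (-1.47 ± 0.27). The G protein gene Gnai1 (2.48 ± 0.40), Fitm1 (1.93 ± 0.41), the tropomyosin gene Tpm2 (1.76 ± 0.41), sulfiredoxin, Srxn1 (1.62 ± 0.34), and Lgals1 (1.52 ± 0.24) rose, with Serpina7 (1.47 ± 0.27), Id1 (1.46 ± 0.36) and nocturnin, Noct (1.36 ± 0.20). Adjusted p-values in limma were between 2.1e-06 and 0.047. No S range holds arrays of both groups, so S range and loss of Myd88 differ together in this comparison. Myd88 and Lars2 averaged under log2 4 in Ager_Myd88_null and Itga9 in Ager_null, and with such values set to 4 Myd88 was at -1.91 and Lars2 at -1.30, while Itga9 (0.47) lost the call.

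These livers differed from Ager_null in 208 genes, 136 higher and 72 lower, with 160 of them and 714 of all tested genes not overlapping (chance 0.952%) and 1936 at an unadjusted p under 0.05. Of 32 acute phase and IL-6/STAT3 genes 4 fell, Pim1, Lbp (-0.70 ± 0.16), Il1r1 (-0.93 ± 0.23) and Itih3 (-0.37 ± 0.10), and 9 passed when adjusted over the list alone, 8 of them lower (camera adjusted p = 2.5e-05, median -0.23). Of 19 NF-kB targets Nfkbiz fell (-1.13 ± 0.28), and 5 passed when adjusted over the list alone (camera adjusted p = 0.00017, median -0.47). Of 15 glucocorticoid-responsive genes 3 fell, Fkbp5, Lpin1 (-0.90 ± 0.21) and Klf9 (-0.85 ± 0.22, adjusted p = 0.0513 with values under log2 4 set to 4), and 5 when adjusted over the list alone (camera adjusted p = 0.00041, median -0.19). All 20 gluconeogenesis and glycogen genes stood lower (camera adjusted p = 2.5e-05, median -0.18), 1 of them called, Ppp1r3b, which targets a phosphatase to glycogen (-0.88 ± 0.19), and 3 when adjusted over the list alone. With an estimated correlation the adjusted p of the 4 lists was 0.411, 0.388, 0.411 and 0.411.

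Heat shock genes (2 of 15 fell, Hspd1 by 0.46 and Chordc1 by 0.78, and 6 when adjusted over the list alone) and ER stress genes (2 of 23 fell, Creld2 by 0.85 and Syvn1 by 0.90, and 3 over the list alone) were shifted down, with camera adjusted p of 0.00027 and 0.0080. Fatty acid and triglyceride genes (1 of 22 fell, Lpin1, and 1 when adjusted over the list alone) and hepatocyte markers (0 of 15, also 0 over the list alone, median -0.05) passed at 0.034 and 0.049, the latter at 0.0906 with quantile normalization. With an estimated correlation the adjusted p was 0.411 for heat shock and ER stress genes and 0.629 for the last pair. The Toll-like receptor pathway did not pass as a list (camera adjusted p = 0.86, median 0.08, mean -0.0038), but 4 of 20 members were called, Tollip (0.38 ± 0.10) and Irf7 (1.05 ± 0.27) higher and Lbp and Il1r1 lower, and 5 when adjusted over the list alone. Its adjusted p with an estimated correlation was 0.914. In the other 24 lists, 6 members were called. With median centring the split of called genes was 62 higher and 93 lower. A block for the S range gave 120 called genes, 100 higher and 20 lower and 31 of them among the 208, while fatty acid, ER stress, heat shock and hepatocyte lists had adjusted p-values of 0.859, 0.0839, 0.331 and 0.217, and no S range holds both groups.

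Where Myd88 was already absent, livers that also lacked Ager had higher H2-Bl (2.98 ± 0.26), Meiob (1.91 ± 0.31), Tubb5 (0.89 ± 0.15) and Glo1, which encodes glyoxalase 1 (0.62 ± 0.11), all on chromosome 17, and also Setdb2 (1.46 ± 0.24), Setd4 (1.33 ± 0.26) and Nip7 (0.86 ± 0.17). They had lower Tedc2 (-3.02 ± 0.40), Zfp944 (-1.19 ± 0.23) and Gfer (-0.87 ± 0.17) on chromosome 17, and G0s2, an inhibitor of triglyceride lipase (-4.24 ± 0.75), Brd3 (-1.29 ± 0.25) and Ppp1r3b (-1.08 ± 0.21) elsewhere. Adjusted p-values in limma were between 6.5e-06 and 0.046, and Brd3 (-0.88) lost the call with values under log2 4 set to 4. These 13 genes, 7 higher and 6 lower, were all that was called, and the groups did not overlap for all 13, as for 503 of all tested genes (chance 2.86%). At an unadjusted p under 0.05 there were 1370 genes. Gfer has the opposite sign with the mean of its probe sets (0.77). Myd88 was at -0.04 (adjusted p = 0.954).

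In this comparison 6 lists were shifted. Immediate early genes (camera adjusted p = 0.0035, median -0.30, 3 of 30 adjusted over the list alone, with Junb at -0.87 ± 0.20), IL-6/STAT3 genes (0.0041, median -0.15, 1 of 32, Il6ra at -1.25 ± 0.34) and fatty acid synthesis (0.00018, median -0.39, 1 of 22, Acly at -0.68 ± 0.18) were lower. So were gluconeogenesis and glycogen genes (0.0035, median -0.18, 2 of 20, with Irs2 at -1.91 ± 0.45) and clock genes (0.00026, median -0.63, 3 of 16, with Hlf at -1.29 ± 0.28 and Per2 at -1.93 ± 0.52). Kupffer cell markers were higher in 17 of 17 members (0.00089, median 0.52, 0 adjusted over the list alone), and without Myd88_null 4 the adjusted p was 0.574. With an estimated correlation the adjusted p was between 0.657 and 0.878 for these lists. In the other 27 lists, 1 member was called. A block for the S range gave 5 called genes, 3 of them among the 13, whose median size was 1.17 within S 1 to 6 and 1.33 within S 7 to 12.

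Between the single deletions, Ager_null was higher than Myd88_null for H2-Bl (2.90 ± 0.23), Ddit4, an inhibitor of mTORC1 (2.83 ± 0.55), Myd88 (2.42 ± 0.24), Limd1 (2.40 ± 0.26), Lars2 (2.10 ± 0.16), Abca3 (1.75 ± 0.37), Pla2g7 (1.71 ± 0.32), Serpina4-ps1 (1.53 ± 0.35) and Setdb2 (1.44 ± 0.22). It was lower for Gnai1 (-2.77 ± 0.40), Zfp991 (-2.55 ± 0.39), Dclre1a (-2.54 ± 0.44), Zfp979 (-2.46 ± 0.28), Tpm2 (-2.21 ± 0.41), Fitm1 (-1.99 ± 0.41), Lgals1 (-1.84 ± 0.24), Znf41-ps (-1.81 ± 0.28) and Tedc2 (-1.79 ± 0.36). Adjusted p-values in limma were between 7.7e-07 and 0.036. When values under log2 4 were set to 4, Myd88 was at 1.91, Lars2 at 1.30 and Zfp979 at -1.48. In all 107 genes differed, 31 higher and 76 lower in Ager_null, with 95 of them and 334 of all tested genes not overlapping (chance 0.952%) and 1352 at an unadjusted p under 0.05.

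Here 6 lists were shifted up in Ager_null relative to Myd88_null. They were NF-kB targets (camera adjusted p = 0.0087, median 0.23, 3 of 19 adjusted over the list alone), cholesterol synthesis (0.0012, median 0.30, 0 of 20), ER stress (0.0012, median 0.18, 2 of 23), heat shock (0.0037, median 0.19, 4 of 15, with Bag3 lower at -0.98 ± 0.31), Kupffer cell markers (0.0012, median 0.41, 0 of 17) and stellate cell markers (0.0044, median 0.38, 2 of 13). The adjusted p with an estimated correlation was between 0.578 and 0.76. Col1a2 was the called member (0.80 ± 0.16, but not with values under log2 4 set to 4, at 0.34), and the smallest p of the other lists belonged to Irf1 (0.47 ± 0.13), Fdps (0.68 ± 0.29), Manf (0.53 ± 0.15), Stip1 (0.50 ± 0.15) and Csf1r (0.63 ± 0.22). The Kupffer cell score of Myd88_null 4 was -1.74, and without that array the adjusted p of this list was 0.772. In the other 27 lists, 5 members were called. The split was 38 higher and 51 lower with quantile normalization and 91 and 52 with median centring. With the S range as a block 386 genes were called, 79 of them among the 107, and NF-kB, ER stress and heat shock lists had adjusted p-values of 0.103, 0.0573 and 0.487. Against Myd88_null 4, the Myd88_null array in the S range of Ager_null and part of the group on which the genes were called, their median size was 1.13.

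The interaction asks whether loss of 1 gene changes the effect of losing the other. It was negative for G0s2 (-3.82 ± 0.98), Ctse (-3.75 ± 0.72), Foxq1 (-3.23 ± 0.65), Fat1 (-2.88 ± 0.64), Pim1 (-2.83 ± 0.48), the insulin receptor substrate gene Irs2 (-2.82 ± 0.60), Zfp36l2 (-2.70 ± 0.69), Slc45a3 (-2.59 ± 0.50), Tacc2 (-2.51 ± 0.63) and Plec (-2.17 ± 0.52). Pim1, for example, averaged 5.95 ± 0.52 in WT (n = 5), 7.57 ± 0.73 in Ager_null (n = 6), 6.70 ± 0.42 in Myd88_null (n = 4) and 5.49 ± 0.38 in Ager_Myd88_null (n = 4). Adjusted p-values of the 10 genes in limma were between 0.025 and 0.049, and G0s2 and Zfp36l2 were at 0.0507 and 0.0504 with values under log2 4 set to 4. There were 205 genes with an interaction, 49 positive and 156 negative, and 2319 at an unadjusted p under 0.05. Relative to WT, the 156 had median changes of 0.609 in Ager_null, 0.687 in Myd88_null and 0.0368 in Ager_Myd88_null, where 89 lay above WT and 67 below. For the 49 these were -0.59, -0.443 and 0.0706, with 35 above WT and 14 below in Ager_Myd88_null. The genes were called by the interaction itself, so these medians describe them and test nothing.

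**Figure D3:**
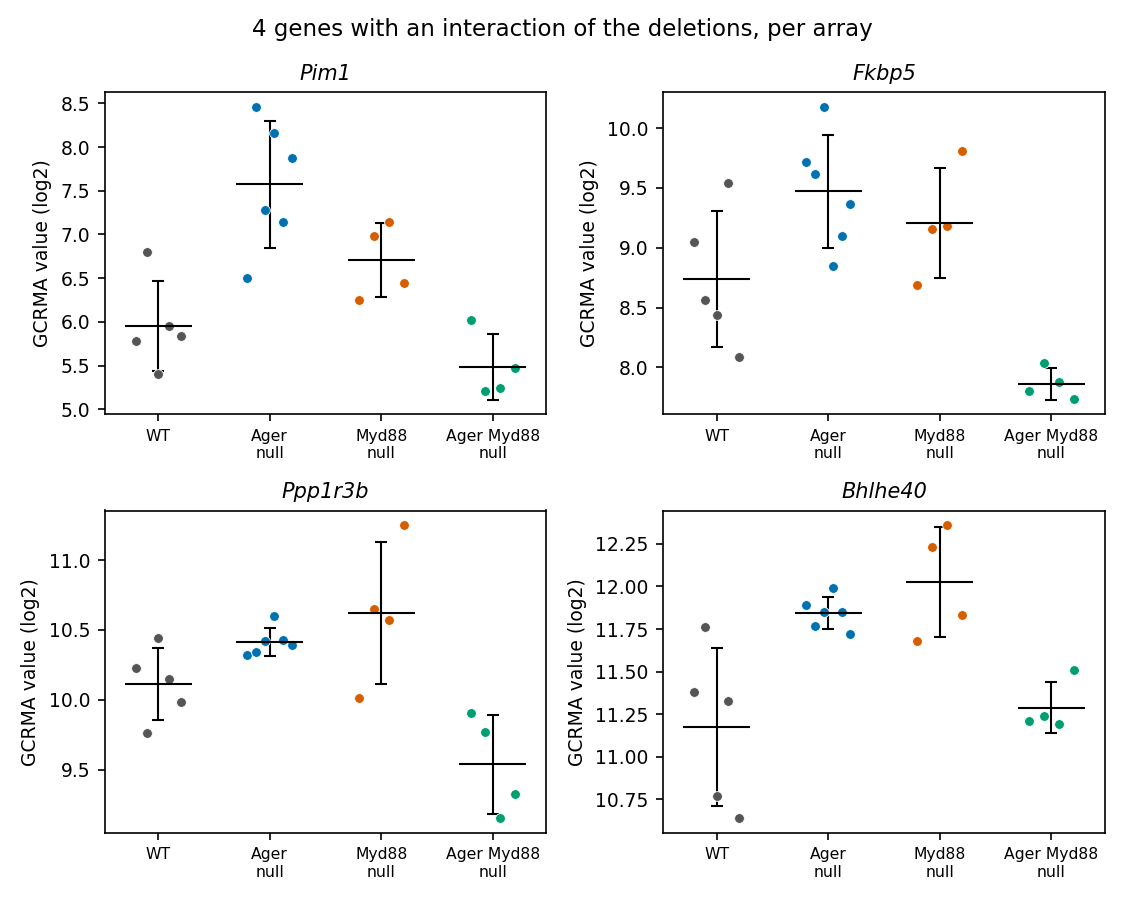
GCRMA values (log2) of Pim1, Fkbp5, Ppp1r3b and Bhlhe40 per array, 4 of the named genes picked for display after their values were seen, with group means as lines and SDs as bars. Fkbp5 averaged 8.74 in WT, 9.47 in Ager_null, 9.21 in Myd88_null and 7.86 in Ager_Myd88_null.

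Of 15 glucocorticoid-responsive genes 5 had a negative interaction, among them Fkbp5 (-2.08 ± 0.40), Zbtb16 (-1.01 ± 0.20), Pik3r1 (-1.80 ± 0.44) and Lpin1 (-1.26 ± 0.31), and 7 passed when adjusted over the list alone, 6 negative and 1 positive (camera adjusted p = 0.034, median -0.46). Gluconeogenesis and glycogen genes had 2 of 20, Ppp1r3b (-1.39 ± 0.28) and Irs2, and 6 over the list alone (0.00085, median -0.36). IL-6/STAT3 genes had 2 of 32, Pim1 and Lbp (-0.95 ± 0.24), and 6 over the list alone (0.0074, median -0.23). Clock genes had 1 of 16, Bhlhe40 (-1.40 ± 0.26), and 6 over the list alone (0.021, median -0.65), and fatty acid genes 1 of 22, Lpin1, and 4 over the list alone (0.0074, median -0.41). Heat shock genes had 0 of 15 and 3 over the list alone (0.037, median -0.39). ER stress genes did not pass as a list (0.51) but 3 of 23 were called, also 3 over the list alone, Creld2 (-1.18 ± 0.28) and Syvn1 (-1.34 ± 0.33) negative and Atf4 (1.42 ± 0.35) positive. Kupffer cell markers had 0 of 17, also 0 over the list alone, and a positive shift (0.0052, median 0.88). With an estimated correlation the adjusted p was 0.772 for each of these lists. Leaving out 1 array ended the camera call of the Kupffer cell list for Myd88_null 4 (0.0723), of the clock list for Ager_null 6 (0.0608) and of the glucocorticoid list for WT 2, Myd88_null 3 and Ager_Myd88_null 4 (0.0651, 0.0814 and 0.0517). The heat shock list lost its call without WT 1 or 2, Ager_null 4 or 5, Myd88_null 1, 3 or 4, or Ager_Myd88_null 2, 3 or 4 (adjusted p between 0.0552 and 0.109). In the other 25 lists, 6 members were called. The split was 84 positive and 129 negative with quantile normalization and 69 and 120 with median centring. With the S range as a block, limma called 0 genes (1128 at an unadjusted p under 0.05), and fatty acid, clock, heat shock and Kupffer cell lists had adjusted p-values of 0.326, 0.326, 0.603 and 0.865.

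Called genes were more frequent near the deleted loci than elsewhere. Among the 150 annotated genes on each side of Ager, 5 of 87 tested genes (5.75%) were called in Ager_null against WT, among 8428 others 1.21% (Fisher's exact test, p = 0.00466, adjusted p over loci and comparisons 0.0109). Over all of chromosome 17, 17 of 401 tested genes were called, 9 higher and 8 lower (Fisher's exact p = 9.2e-06). Around Myd88, 6 of 60 tested genes (10.0%) were called in Myd88_null against WT and 0.319% of 8454 others (Fisher's exact p = 9.1e-08, adjusted 1.3e-06). These were 3 higher and 3 lower genes besides Myd88, Lars2 and Limd1 among them. Over all of chromosome 9, 8 of 480 tested genes (1.67%) were called, 5 higher and 3 lower (Fisher's exact p = 0.000382). With 50 genes on each side the share near Ager was 2.78% (Fisher's exact p = 0.366). In Ager_Myd88_null, 2 of the 87 genes near Ager were called against WT (Fisher's exact p = 0.0307, adjusted 0.0537) and 2 against Myd88_null (0.00748, adjusted 0.0150).

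**Figure D4:**
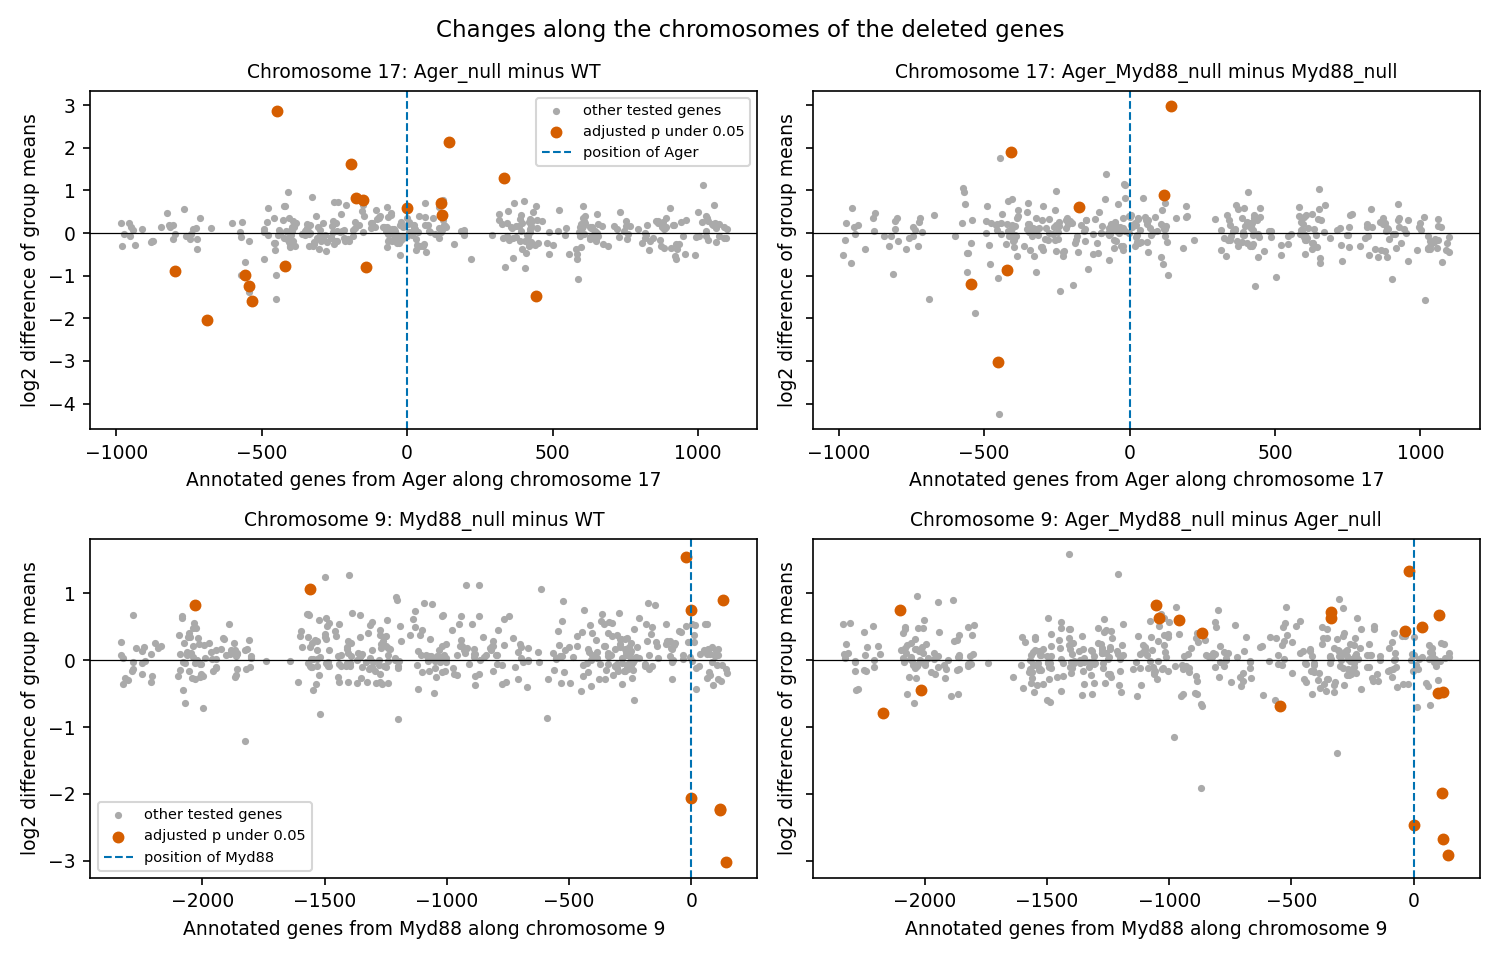
Log2 difference of group means of tested genes along chromosomes 17 (top) and 9 (bottom), against the number of annotated genes from the deleted gene; each point is a gene, orange points have an adjusted p under 0.05 and the dashed line marks Ager or Myd88. H2-Bl, at 2.13 in Ager_null against WT, was at 2.98 in Ager_Myd88_null against Myd88_null, and Lars2, at -2.23 in Myd88_null against WT, was at -1.98 in Ager_Myd88_null against Ager_null.

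Counts of called genes moved when single arrays were left out. They ran from 16 (without WT 5) to 403 (without Myd88_null 1) for Ager_null against WT, from 10 (without Myd88_null 4) to 987 (without Myd88_null 1) for Myd88_null against WT, and from 18 to 34 for Ager_Myd88_null against WT. Against Ager_null, Ager_Myd88_null gave 18 (without Ager_Myd88_null 3) to 368 (without Myd88_null 1) genes, and against Myd88_null 2 (without Myd88_null 4) to 446 (without Myd88_null 1). Between the single deletions the range was 30 (without Myd88_null 4) to 179 (without Ager_null 6). For the interaction limma called 0 genes without Myd88_null 3, Myd88_null 4 or Ager_Myd88_null 3 (1863, 1667 and 1761 at an unadjusted p under 0.05) and 1739 without Myd88_null 1.

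Ager_null and Myd88_null shared 7 called genes relative to WT, all higher, where independent lists would share 0.225 higher and 0.0296 lower genes. Both comparisons use the same WT arrays. Across genes, which are not independent replicates, their log2 changes correlated at r = 0.525. Simulated groups without any effect, in which genes were drawn independently, gave 0.491. The covariance was 0.0601 against a simulated 0.0229. With the WT arrays split into 2 and 3, the median over 20 splits was r = 0.300, with a median of 0 shared calls and at most 1. With so few WT arrays the calls themselves ran from 0 to 276 for Ager_null and from 4 to 30 for Myd88_null. The few shared calls therefore cannot be told apart from lost power.

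The remaining lists passed camera in 0 of the 7 comparisons. The lowest adjusted p was 0.0643 for bile acid synthesis and transport (25 tested members, 2 calls over all comparisons), 0.0656 for interferon-stimulated genes (27 members, 2 calls) and 0.104 for PPAR-alpha targets and fatty acid oxidation (30 members, 0 calls). It was 0.115 for NRF2 targets and antioxidant genes (23 members, 3 calls), 0.161 for regeneration growth factors and matrix proteases (20 members, 1 call), 0.397 for p53 targets and cell cycle inhibitors (17 members, 0 calls) and 0.481 for the cell cycle (14 members, 0 calls). It was 0.58 for RAGE ligands and effectors (14 members, 6 calls), 0.626 for apoptosis and survival (20 members, 1 call), 0.171 for neutrophil and monocyte markers (3 members), 0.199 for lymphocyte markers (4 members) and 0.411 for endothelial markers (15 members). The 6 calls of the RAGE list were repeated calls of Glo1 and Mapk14, both on chromosome 17 with Ager, with at most 1 member in any comparison. Sex-linked genes, a check with 3 members, had 0.0964. The cholangiocyte list had 2 tested members and the kidney, erythroid, exocrine pancreas and adipose lists 1 each, with 0 calls.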

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

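The tests of linkage on chromosomes 17 and 9, of single arrays, of the S range and of another cell type were chosen after the results were seen; the counts over other splits of the arrays and the test of other probe sets were planned.

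Called genes clustered on the chromosome of the deleted gene. Of 17 genes called on chromosome 17 in Ager_null against WT, 88.24% had the same sign in Ager_Myd88_null against Myd88_null, a comparison that shares no array. Of 90 called elsewhere 26.7% did (Fisher's exact p = 2.6e-06). The same sign came with an unadjusted p under 0.05 in limma for 12 of the 17 and 3 of the 90. A genotype carried along with the Ager deletion may account for the chromosome 17 genes that kept their sign. Pim1 (1.62 and -1.22) and Wtap (-0.89 and 0.34) reversed it. On chromosome 9 only genes within 150 of Myd88 on each side were taken, whereas chromosome 17 was taken whole. The share with the same sign in Ager_Myd88_null against Ager_null was 83.33% of these 6 genes and 33.3% of 27 others (Fisher's exact p = 0.0616). These are too few to decide for the set. Kank2 (0.83 and -0.09) and C2cd2l (1.07 and -0.26), called on chromosome 9 outside this window, reversed sign and count among the 27. Of the 6, 4 had the same sign at an unadjusted p under 0.05, so the same account may hold for these 4. They were Lars2, Limd1, Itga9 and the gene model 2010315B03Rik, singled out after its values were seen. A sequence difference under single probe sets stays open for the set. Of 13 other probe sets, from 10 genes of chromosome 17 in Ager_null against WT, 76.92% moved the same way at an unadjusted p under 0.05 in limma. The binomial interval was 46.2% to 95.0%, and it treats probe sets of 1 gene as independent. Those of Abca3, Cbs, Glo1, Pim1, Riok2, Zfp944 and 1700001C19Rik moved the same way. Gfer moved the opposite way, Tubb5 and Wtap did not pass, and none was tested for chromosome 9. An effect of the missing genes on their neighbours was not tested.

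Of the 205 interaction genes 156 were negative. An effect of Myd88_null 4 alone stays open: without it 0 genes passed in limma (1667 at an unadjusted p under 0.05) and the estimates stood at a median ratio of 0.917, but leaving out any of 10 other arrays also lowered the count by over 1.5 times, and the genes had been called with all arrays. The S range cannot be told apart from the interaction, since as a block it left the estimates at a median ratio of 0.963 and a median size of 1.21 before and 1.16 after (log2), but raised the median SE from 0.277 to 0.376, so that 0 genes passed in limma (1128 at an unadjusted p under 0.05). Another cell type in Myd88_null 4 also stays open, since no list of at least 3 markers of a cell type other than hepatocytes exceeded the highest other array (largest excess -0.4083) while a cholangiocyte list of 2 members and a kidney and glomerulus list of 1 did, by 1.23 and 0.224. The other markers of this pair of lists, of 11 and 13 on the array, were under the filter. A loss of cells was not covered: Kupffer cell markers read 6.95 in this array and at least 8.115 in every other, and lymphocyte markers 4.478 and at least 5.035. A dependence of the effect of losing Myd88 on Ager, which the design names, stays open as well.

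The genes that set Ager_null apart may in part follow the S range, which all 6 Ager_null arrays share with WT 5. On genes called without WT 5, that array lay at -6.119% of the way from the other WT arrays to Ager_null, and 1 array excludes nothing. With the S range as a block 11 of the 107 genes were still called. Of these 11, 6 lie on chromosome 17, which holds 17 of the 107. The median size of the 107 stayed at 0.80 (log2) while the median SE rose from 0.172 to 0.243. In a fit with groups, 115 genes had an S range term at an adjusted p under 0.05 (108 without Myd88_null 4). Deviations from the group means correlated at a median r of 0.00419 within S ranges and 0.0131 across them. All 6 Ager_null arrays lie in the same S range, so subtracting their group mean also removes any S range effect they share. Pairs with an Ager_null array therefore cannot show such an effect, and these correlations do not decide on it for Ager_null. S range and Ager deletion cannot be told apart from the arrays of this study for the genes that lost the call. For Ager_Myd88_null against Ager_null no S range holds both groups, and 31 of the 208 genes were still called with the block. S range and loss of Myd88 cannot be told apart there for the other genes.

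Counts over other splits of the arrays treat them as exchangeable and ignore the S range, so they bear only on a chance assignment of arrays to groups. Among 100 splits, the real one included, 1 gave as many genes as the 107 of Ager_null against WT (highest other 74), 1 as many as the 208 of Ager_Myd88_null against Ager_null (highest other 12) and 1 as many as the 107 between the single deletions (highest other 61). This argues against chance in this sense there but does not exclude it. The other splits mix the genotypes compared, which adds genotype differences to their spread, and the ranks were not adjusted over the comparisons. With the S range as a block 11, 31 and 79 of the genes called in these comparisons were still called. For the 205 genes of the interaction it was 1 of 100 (highest other 4), but these splits mix all 4 genotypes, which likewise adds genotype differences to the spread, and with the block 0 of the 205 passed in limma (1128 genes at an unadjusted p under 0.05). For the 27 genes of Ager_Myd88_null against WT it was 1 of 100, and the highest other, with 20 genes, set WT 1 and 2 and Ager_Myd88_null 1 and 2, the arrays of these groups in S 1 to 6, against the rest, while the block gave 26 genes, 23 of them among the 27. For the 34 genes of Myd88_null against WT it was 4 of 100, but another split called 414, several times the real count, which points to a structure of the samples. For the 13 genes of Ager_Myd88_null against Myd88_null, 2 of 35 splits gave as many (highest other 159), so chance cannot be excluded.

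Single arrays stood apart from their group for 28 of 516 groups of gene values, where chance gives about 5%. H2-Bl read 7.63 in WT 4 (nearest 6.99) and 9.73 in Ager_null 6 (9.16), Riok2 7.15 in Ager_Myd88_null 4 (7.72), Acyp2 9.18 in Myd88_null 1 (8.32) and Jup 7.36 in Myd88_null 4 (6.24). Setdb2 was at 8.74 in Myd88_null 3 (8.38), Gucy1a1 at 5.61 in WT 3 (5.44), Gfer at 10.89 in Myd88_null 1 (10.49), Fitm1 at 8.68 in WT 4 (9.49) and Id1 at 5.90 in Myd88_null 4 (6.92). Trim2 was at 7.03 in Myd88_null 1 (8.05) and 6.26 in Ager_Myd88_null 4 (7.10), Glo1 at 13.66 in Ager_null 1 (13.85), Zfp36l2 at 9.31 in Myd88_null 1 (10.72), Slc45a3 at 5.98 in Ager_null 6 (7.25) and Irs1 at 6.51 in Ager_null 1 (7.71). Col1a2 read 3.27 in Ager_Myd88_null 2 (3.80), Ccl2 5.76 in Ager_null 2 (4.60), Ier2 9.50 in Ager_Myd88_null 1 (10.28), Lss 8.03 in Ager_null 6 (9.20) and Per2 4.98 in Ager_Myd88_null 4 (4.30). Tollip read 8.34 in WT 2 (8.60), Fads2 11.45 in Ager_null 3 (11.17), Creld2 9.98 in Ager_Myd88_null 2 (10.42) and Fdps 11.45 in Ager_null 6 (12.52). Cd163 read 9.76 in WT 4 (9.02), Bhlhe40 11.51 in Ager_Myd88_null 4 (11.24) and Atf4 9.14 in WT 1 (9.96). Myd88_null 4 had a Kupffer cell score of -1.74 (nearest -0.11) and a median correlation with other arrays of 0.965 (0.983).

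The interaction term passed in limma, in the fit without blocks and with all arrays, for G0s2 (-3.82), Ctse (-3.75), Foxq1 (-3.23), Fat1 (-2.88), Pim1 (-2.83), Irs2 (-2.82), Zfp36l2 (-2.70), Slc45a3 (-2.59), Tacc2 (-2.51), Plec (-2.17) and Fkbp5 (-2.08). It also passed for Pik3r1 (-1.80), Bhlhe40 (-1.40), Ppp1r3b (-1.39), Syvn1 (-1.34), Lpin1 (-1.26), Creld2 (-1.18), Zbtb16 (-1.01), Lbp (-0.95) and Atf4 (1.42). Among 1147 tested probe sets without a gene name, 25 differed in Ager_null and 6 in Myd88_null against WT, 6 in Ager_Myd88_null against WT, 44 against Ager_null and 14 against Myd88_null, 22 between the single deletions and 22 in the interaction.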

How the results depend on the processing

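List tests under the blocks and other scalings, and the whole-chromosome counts, were chosen after the results were seen. Of the single-gene values, 2018 kept their direction and their side of the threshold under the alternatives other than leaving out an array, 288 lost the call, 44 gained one and 2 reversed. The latter are Gfer at 0.87 in Ager_Myd88_null against WT and 0.77 against Myd88_null with the mean of its probe sets, which move in opposite directions. For lists, 148 tests kept their side of the threshold and 108 lost the call. Leaving out 1 array, 3123 single-gene values stayed on their side, 696 lost the call and 38 gained one, and 749 list tests stayed on their side and 66 lost the call. In Ager_null against WT heat shock genes lost the call without 5 arrays (highest adjusted p 0.108), and in Ager_Myd88_null against WT immediate early genes did without 5 (0.111), fatty acid genes without 4 (0.176), the clock without 2 (0.0988), glucocorticoid-responsive genes without 4 (0.113) and xenobiotic metabolism without 9 (0.135). Against Ager_null fatty acid genes did without 4 (0.132) and hepatocyte markers without 14 (0.126), and against Myd88_null immediate early and IL-6/STAT3 genes without Myd88_null 3 (0.0667). The Toll-like receptor list in Ager_Myd88_null against Ager_null, not called, changed sign with the S range block (adjusted p = 0.486), the replicate block (0.897) and without Ager_Myd88_null 1 (0.991) or 2 (0.875), and ranged down to 0.603 (without Ager_Myd88_null 4) over the arrays left out. With the replicate block hepatocyte markers in Ager_Myd88_null against Ager_null (adjusted p = 0.0552), xenobiotic metabolism in Ager_Myd88_null against WT (0.110) and the clock in the interaction (0.0630) lost the call. Signal over background limits what could be tested, as 9678 genes were under the filter.

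The cause was not tested for the following counts except where fewer genes or samples enter. For Ager_null against WT the count was 43 without a filter, 711 with array weights, 33 with only these groups, 59 with the S block and 29 at a change of at least 1. For Myd88_null against WT it was 12 with the filter at 6, 11 with quantile normalization, 12 with median centring, 785 with weights, 7 with only these groups, 86 with the S block and 18 at a change of at least 1. For Ager_Myd88_null against WT it was 42 with weights, 46 with the replicate block and 16 at a change of at least 1, and against Ager_null 91 without a filter, 619 with weights, 138 with the replicate block, 120 with the S block and 58 at a change of at least 1. Against Myd88_null it was 293 with weights, 4 with only these groups, 3 with the replicate block and 5 with the S block. Between the single deletions it was 461 with weights, 28 with only these groups, 386 with the S block and 45 at a change of at least 1. Interaction genes numbered 76 without a filter, 1382 with weights, 37 with the replicate block and 0 in limma with the S block (1128 at an unadjusted p under 0.05). Array weights ran from 0.318 (Myd88_null 4) to 3.24 (Myd88_null 2). Near Ager 2.78% of genes were called with 50 genes on each side, and with the WT arrays split the median of shared calls was 0. Replicate numbers were not taken to pair the arrays. Of 25 same-number pairs 9 correlated above 0.1, with a median r of 0.052 against 0.0047 for other pairs. Only 3 of 19 arrays correlated best with their own number, and in limma 0 genes had a replicate number term at an adjusted p under 0.05. A weak pairing is not excluded by these values.

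Leaving out replicates in order, Ager_null against WT had 42, 19, 235, 56 and 16 genes without WT 1 to 5, 41, 28, 45 and 28 without Ager_null 2 to 5, 403, 62 and 253 without Myd88_null 1, 2 and 4, and 65, 66, 64 and 59 without Ager_Myd88_null 1 to 4. Myd88_null against WT had 18, 66, 15 and 18 without WT 2 to 5, 65 without Ager_null 6 and 987, 11, 18 and 10 without Myd88_null 1 to 4. Ager_Myd88_null against Ager_null had 114, 112 and 135 without WT 1, 2 and 4, 138, 131, 44, 58 and 110 without Ager_null 1, 2, 3, 4 and 6, 368, 92 and 126 without Myd88_null 1 to 3 and 83, 111, 18 and 48 without Ager_Myd88_null 1 to 4. Against Myd88_null it had 7, 8, 7 and 8 without WT 1, 2, 4 and 5, 446, 3, 6 and 2 without Myd88_null 1 to 4 and 8, 2 and 8 without Ager_Myd88_null 1, 3 and 4. Between the single deletions there were 66, 63, 50, 61 and 179 without Ager_null 1, 3, 4, 5 and 6 and 46 and 30 without Myd88_null 2 and 4. The interaction had 105, 29, 474 and 24 without WT 1, 2, 3 and 5, 320, 28 and 91 without Ager_null 1, 3 and 5, 1739, 10, 0 and 0 without Myd88_null 1 to 4 and 109, 0 and 2 without Ager_Myd88_null 2 to 4, the counts of 0 in limma having 1863, 1667 and 1761 genes at an unadjusted p under 0.05.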

Other observations

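The genes below were singled out after their values were seen. Igha, an immunoglobulin heavy chain gene, averaged 3.95 ± 0.23 (log2, SD, n = 5) in WT, 5.30 ± 0.32 (n = 6) in Ager_null, 5.98 ± 0.97 (n = 4) in Myd88_null and 6.12 ± 0.25 (n = 4) in Ager_Myd88_null. Postn, which encodes periostin, averaged 7.01 ± 0.28, 7.93 ± 0.28, 8.35 ± 0.49 and 8.18 ± 0.21 in the same order. The chemokine gene Cxcl10 averaged 6.22 ± 0.95, 5.22 ± 0.62, 4.78 ± 0.32 and 4.34 ± 0.19, and Cxcl1 11.27 ± 0.88, 10.20 ± 1.91, 8.96 ± 0.68 and 7.57 ± 1.59.

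The effect of losing Ager was set against itself in livers with and without Myd88, which share no array. Across genes, which are not independent replicates, the log2 changes correlated at r = -0.293, and 39 of the 107 genes called in Ager_null against WT had the same sign in Ager_Myd88_null against Myd88_null. Both called 5 genes, 3 higher and 2 lower, where independent lists would share 0.0584 and 0.0254, and 0 of the 5 lie off the chromosomes of the deleted genes. The effect of losing Myd88 with and without Ager correlated at r = -0.227, with 6 genes called in both, 2 higher and 4 lower. Only 1 of the 6 lies off the chromosomes of the deleted genes. The 4 lower genes were Myd88 itself, Lars2, Limd1 and the gene model 2010315B03Rik, and Itga9 was among the higher, all on chromosome 9.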
